A study of Mus musculus with 8 samples.

How the data were processed

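RNA labelled as brain tumor or naive brain tissue, from a mouse model of ZFTA-RELA driven supratentorial ependymoma, was sequenced in 8 libraries. The labels give all 8 the fusion as genotype and the drug name as cell line, the naive and vehicle libraries included, and do not say whether naive brain came from mice with a tumor. Both fields were read as naming the model and the study. The libraries form 4 groups of 2, by treatment (vehicle or MRX-2843, an inhibitor of the receptor tyrosine kinases MERTK and FLT3) and tissue. Per the labels, mice with a tumor seen by MRI were randomised, dosed by oral gavage with vehicle or 50 mg/kg MRX-2843 once a day for 5 days, and killed 1 h after the last dose. RNA was extracted with a GenCatch kit, and an outside company prepared the libraries for Illumina sequencing. The labels call the 2 libraries of a group duplicates and do not say whether they come from separate animals, so the p-values may measure technical spread only. A number in the column names, 909 for all MRX-2843 libraries, 914 or 915 for vehicle, is not explained, and treatment cannot be separated from it.

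The deposited table holds raw read counts per gene, in whole numbers, for 55414 genes. The submitters' notes name STAR 2.7.7a, SAMtools, featureCounts and Subread and the builds hg38 and mm10, without the role of each or their order; the strand setting, the gene annotation and any trimming are not stated. Library totals ran from 51150569 to 112938462 counts. A count of 0 in a library allows up to 3 counts, which is 0.0266 to 0.0587 CPM (counts scaled to a common library total). Intervals and floors cover counting error only. Coordinates are from GENCODE M21 on GRCm38. Of the gene identifiers, 52133 (94.1%) matched that release without their version number and 35 with it, so the annotation behind the counts was another release. CPM values are over library totals scaled by TMM, except where a raw CPM is named.

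Counts were fitted with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group with its minimum count of 10, quasi-likelihood fit of 4 group means with 4 residual degrees of freedom, common biological coefficient of variation 21.0%). Of the genes, 24356 passed the filter. The 5 comparisons were tumor against naive brain within each treatment, MRX-2843 against vehicle within each tissue, and the interaction of treatment and tissue. Changed genes are those with a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test, without a minimum fold change. Standard errors (SE) are the absolute log2 fold change over the square root of the F statistic. Gene lists were compared with all other genes by camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over 32 lists, and again with the correlation estimated from the data. With an estimated correlation camera reads its statistic on the 4 residual degrees of freedom, and with a preset one on a number set by the genes. A call lost with an estimated correlation may thus reflect the few libraries rather than genes that vary together. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 made the tables and plots.

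The gene lists, 17 of pathways or processes and 15 of cell type markers, the comparisons, the rule for named genes and the first set of alternatives were chosen before the data were examined. Genes are named by this rule: among genes with adjusted p under 0.05, a mean log2 CPM of at least 2, an ordinary symbol and no overlap between the libraries of the groups compared, the 8 largest rises and 8 largest falls for vehicle tumor against naive brain and for the drug in tumor, and 4 of each elsewhere (the interaction without the condition on overlap). To these come up to 4 members of each list with the smallest adjusted p (the most abundant member where none passed), and always Mertk, Flt3, Axl, Tyro3, Rela, Zfta, Ccnd1 and L1cam. Each list's count of changed members is given over all genes tested and adjusted over the list alone. A fold against a group with 0 counts is a lower bound that sets the group at 3 counts in all, and with 1 to 3 counts in the group it is a ratio with a 95% counting interval. Fitted log2 values of such genes depend on the prior count. Lists of brain region markers and of neuroblast markers were written after the first results had been seen.

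Alternatives were DESeq2's median-of-ratios scaling in edgeR, library totals without scaling, DESeq2 1.42.0 as the test, no filter, a stricter filter (CPM of at least 1 in 2 libraries), a replicate block, a block on the number in the column names, only the 2 groups compared, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Leaving out a library leaves a group with 1, which is then assumed to vary like the others. Added after the data were seen were fits without genes on chromosomes X and Y, without mitochondrially encoded genes and their nuclear copies, and without both MRX-2843 tumor libraries, and library totals for the gene lists. Tested on simulated data with known changes in the tumor comparison (22265 genes), edgeR recovered 22 of 67 genes changed by 1.5-fold (32.8%), 42 of 67 changed by 2-fold (62.7%) and 62 of 66 changed by 4-fold (93.9%), with 2 false calls among 128. On the same simulated data DESeq2 made 77 false calls among 230. The simulation gave all groups the vehicle tumor mean and changed few genes, where 14715 of 24356 changed in the real comparison. Its counts were drawn with edgeR's own estimates of spread, so the tools were not compared on equal terms. These rates thus do not carry over to the main fit. A simulated list of 20 genes raised 1.5-fold passed camera's test (adjusted p = 1.83e-18), and 0 of 30 null lists did. The simulated genes were drawn independently, so this does not test lists whose genes vary together. In a computed mixture with 10% vehicle tumor RNA, 344 tumor-high genes gave a median share of 9.72% above MRX-2843 naive brain. The share was taken from the same means as the mixture, so only count noise could move it. It checks the arithmetic of the excess over naive brain, and not the plain percent of the vehicle tumor level. Groups of 2 libraries allow neither a test for outlying libraries nor an informative count of other splits, so none was run, and gene ontology was not searched.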

Results

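The data are counts of RNA-seq reads per gene in supratentorial ependymoma tissue and naive brain of mice. Tumors of this model are driven by the fusion of Zfta with Rela, the gene of an NF-kB subunit. Each of the 4 groups, vehicle naive brain, vehicle tumor, MRX-2843 naive brain and MRX-2843 tumor, held 2 libraries. Totals were 73447881 and 70147859 counts in vehicle naive brain and 75631963 and 78084664 in vehicle tumor. They were 51150569 and 112938462 in MRX-2843 naive brain and 58668926 and 60745017 in MRX-2843 tumor. The comparisons ask how the tumor differed from brain, and whether 5 days of the MERTK and FLT3 inhibitor changed either tissue. Group levels are mean CPM ± SD (n = 2), fold changes are log2 values ± SE from 2 libraries per group, and adjusted p-values are from edgeR's quasi-likelihood test.

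Vehicle tumor was the group that stood apart. Across 16110 genes, Pearson's r between single libraries was 0.974 to 0.975 for vehicle naive brain with MRX-2843 tumor, 0.967 to 0.969 for MRX-2843 naive brain with MRX-2843 tumor, and 0.653 to 0.658 for vehicle tumor with MRX-2843 tumor (genes are not independent replicates). The 2 libraries of each group correlated at 0.994 to 0.996. Mitochondrially encoded genes took 3.26 and 3.37% of the counts in the vehicle tumor libraries, 17.3 and 16.4% in the MRX-2843 tumor libraries, and 14.7 to 18.5% in the 4 naive libraries. The treatments also differed in sex-linked genes: Xist, the RNA that silences an X chromosome, reached 502 to 771 raw CPM in the 4 MRX-2843 libraries and 0.461 to 2.75 in the 4 vehicle libraries. The Y-linked Ddx3y had 2168 to 6717 counts in vehicle libraries and 0 in MRX-2843 libraries. Each contrast of MRX-2843 with vehicle below carries this difference.

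**Figure D1:**
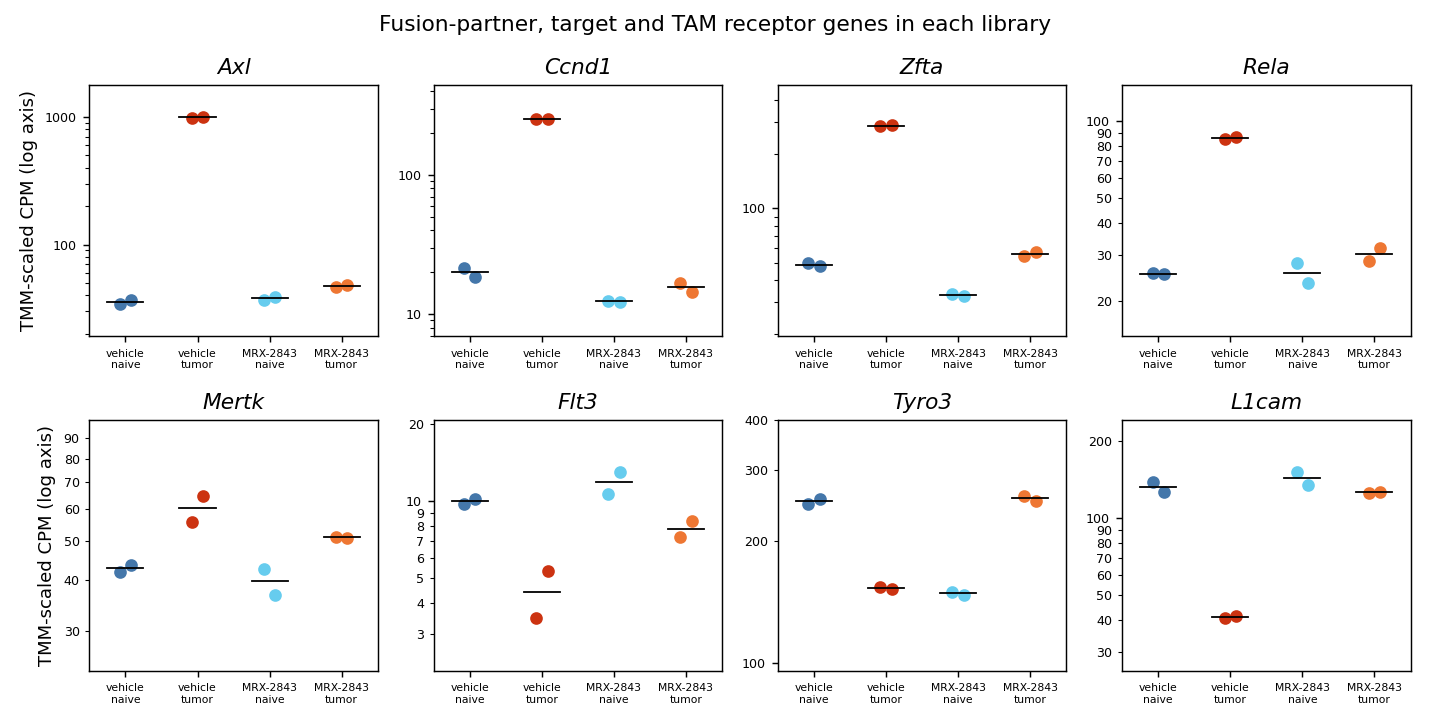
CPM of Axl, Ccnd1, Zfta, Rela, Mertk, Flt3, Tyro3 and L1cam in each library, on log axes that differ between panels, with 1 point per library and a line at the mean of the 2. Axl lies at 991 CPM on average in vehicle tumor and between 35.5 and 47.5 in the other 3 groups.

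In vehicle-treated mice, the tumor expressed interferon, antigen presentation, cell division and matrix genes far above naive brain, and genes of neurons and myelin far below it. Axl, a receptor tyrosine kinase of the TAM family, was at 35.5 ± 1.68 CPM in naive brain and 991 ± 11.7 in tumor (log2 fold change 4.80 ± 0.06, adjusted p = 7.2e-17). Ccnd1, which encodes the G1 cyclin D1, rose from 20.1 ± 2.18 to 253 ± 1.91 CPM (3.66 ± 0.09, adjusted p = 2.7e-14). The fusion partners rose as well, Zfta from 48.6 ± 1.40 to 289 ± 1.87 CPM (adjusted p = 2.4e-14) and Rela from 25.5 ± 0.0728 to 85.6 ± 0.986 CPM (adjusted p = 5e-10), but whether reads of the fusion are counted under either gene is not known. The submitters name a human genome build beside the mouse one without its role. Among the drug's targets, Mertk rose by 0.49 ± 0.09 to 60.3 ± 6.42 CPM (adjusted p = 0.00027) and Flt3 fell by 1.18 ± 0.21 to 4.41 ± 1.33 CPM (adjusted p = 0.00019).

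The largest rises included a growth factor gene pair on chromosome 7, next to Ccnd1 (144929931 to 144939925). Fgf15 (144896531 to 144900953) had 126 ± 7.31 CPM in vehicle tumor and no counts in vehicle naive brain, at least 5760-fold higher, and Fgf4 (144847367 to 144865243) had 37.9 ± 2.55 CPM, at least 1727-fold higher. The imprinted H19 rose to 1301 ± 0.232 CPM (15.36 ± 0.28, adjusted p = 1.1e-15). Hmx1, Mc2r, Oas3, Plac8 and Cst7 had no counts in vehicle naive brain and were at least 2552-fold, 2925-fold, 3016-fold, 3260-fold and 1371-fold higher in tumor. The largest falls were of Hs3st2, Krt12, Lin28b, Ndst4, Serpina9, Gpr6, Gpr101 and Cartpt. Ndst4 fell by 7.66 ± 0.25 from 25.8 ± 1.02 CPM, and Hs3st2 fell by 6.86 ± 0.22 from 37.5 ± 1.58 CPM. Cartpt, a neuropeptide gene, had 2 counts in the tumor libraries, a ratio of 1258 (95% counting interval 348 to 10389) of naive brain to tumor.

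Immune response genes rose together. All 20 measured members of the interferon response list rose (median 7.06, adjusted p = 8.35e-11), Oas2 by 8.25 ± 0.13 and Irf7 by 7.39 ± 0.13. All 15 antigen presentation genes rose (median 6.01, adjusted p = 6.79e-09), among them B2m, the light chain of class I molecules, by 5.62 ± 0.06 and H2-K1 by 6.22 ± 0.07. Homeostatic microglia genes rose in 10 of 10 cases (median 2.50, adjusted p = 3.48e-06; Tmem119 3.64 ± 0.08). Genes of disease-associated microglia rose in 15 of 15 cases (median 3.14, adjusted p = 9.54e-08; Gpnmb 7.69 ± 0.11). Of macrophage and monocyte markers 11 of 12 rose (adjusted p = 7.91e-05; Lyz2 4.73 ± 0.11). Of T and NK cell markers 9 of 10 rose (adjusted p = 0.003; Cd8a 6.27 ± 0.83), and of B cell markers 5 of 6 (adjusted p = 0.0137; Jchain 3.36 ± 0.29). Counts adjusted over the list alone were the same for these lists. The calls of the lymphocyte lists were lost in camera's test with an estimated correlation, at adjusted p = 0.063 for T and NK cells and adjusted p = 0.0957 for B cells. Their estimated correlations, -0.0990 and -0.0528, lay below the preset 0.01, so a stronger correlation is argued against as the cause.

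Dividing-cell and matrix genes rose too. All 20 mitosis genes (median 4.48, adjusted p = 6.68e-08), all 16 cell cycle kinases (median 3.17, adjusted p = 3.48e-06) and 15 of 18 S phase genes (median 2.87, adjusted p = 1.17e-05) rose, while 1 S phase gene fell. The proliferation marker Mki67 rose by 5.68 ± 0.19 to 74.7 ± 0.524 CPM, the topoisomerase gene Top2a by 7.02 ± 0.28 and the replication clamp gene Pcna by 1.70 ± 0.07. Extracellular matrix genes rose in 15 of 16 cases (median 4.18, adjusted p = 9.54e-08; Spp1 7.77 ± 0.09). Mural cell and fibroblast markers rose in 7 of 9 (median 4.80, adjusted p = 0.000379; Col1a1 8.92 ± 0.10) and endothelial markers in 8 of 9 (median 1.42, adjusted p = 0.000393; Vwf 3.02 ± 0.12). Adjusted over the list alone, the counts were the same except that 1 matrix gene also fell and 9 endothelial markers rose.

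All 12 neuron markers fell (median -5.01, adjusted p = 9.54e-08), as did all 10 oligodendrocyte markers (median -4.27, adjusted p = 1.81e-06), with the same counts adjusted over the list alone. Snap25, of the synaptic vesicle fusion machinery, fell by 5.62 ± 0.06 from 2179 ± 66.2 to 44.4 ± 1.90 CPM, and Mbp, encoding myelin basic protein, fell by 4.87 ± 0.05 from 3661 ± 15.6 to 126 ± 0.957 CPM. Of 7 oligodendrocyte precursor markers 5 rose and 1 fell, with the same counts adjusted over the list alone (median 1.26, adjusted p = 0.0427, and adjusted p = 0.141 with an estimated correlation; Sox10 3.43 ± 0.08). This call was lost without MRX-2843 tumor library 1 (adjusted p = 0.0522), without MRX-2843 tumor library 2 (adjusted p = 0.0519) and with library totals (adjusted p = 0.0501). Of radial glia and progenitor genes 9 of 11 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.0196, and adjusted p = 0.141 with an estimated correlation), with the intermediate filament gene Vim at 5.21 ± 0.05 and the neuroblast gene Dcx at -3.39 ± 0.15.

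Signalling lists were mixed. Of 31 measured receptor tyrosine kinases 20 rose and 8 fell (21 and 8 adjusted over the list alone; adjusted p = 0.00362, and adjusted p = 0.141 with an estimated correlation), with Fgfr1 at 3.04 ± 0.07 and Tyro3 at -0.71 ± 0.05. Of 20 NF-kB targets 16 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.000264, and adjusted p = 0.0957 with an estimated correlation; Icam1 7.35 ± 0.11). The listed fusion targets are 13 genes listed as reported to be raised in ZFTA-RELA ependymoma, with the fusion partner Rela among them. Of these 9 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.00605, and adjusted p = 0.094 with an estimated correlation), with Igf2 at 9.04 ± 0.16 and the calcium channel gene Cacna1h at -2.45 ± 0.08. L1cam, the other falling gene of this list, fell by 1.69 ± 0.07 from 133 ± 8.76 to 41.1 ± 0.685 CPM. Of 18 p53 and apoptosis genes 15 rose and 1 fell (15 and 2 adjusted over the list alone; adjusted p = 0.00248, and adjusted p = 0.0607 with an estimated correlation; Cdkn1a 1.53 ± 0.09).

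No call was made for MAPK feedback (9 of 15 rose and 4 fell, adjusted p = 0.0612), which passed with library totals (adjusted p = 0.0454) and without MRX-2843 tumor library 1 (adjusted p = 0.0499) or 2 (adjusted p = 0.0484). Nor was one for the TAM and FLT3 axis (5 of 7 rose and 2 fell, adjusted p = 0.0964), cholesterol synthesis (5 rose and 7 fell of 18, adjusted p = 0.545) or hypoxia and glycolysis (8 rose and 6 fell of 16, adjusted p = 0.704). The same held for immediate early genes (9 rose and 5 fell of 17, adjusted p = 0.545; median 0.42, mean -0.13) and the stress, integrated stress response and heat shock list (7 rose and 6 fell of 15, adjusted p = 0.777; median -0.01, mean 0.38). The astrocyte markers (3 rose and 6 fell of 10, adjusted p = 0.545) and the neutrophil markers (1 rose of 3 measured, adjusted p = 0.37) did not pass. Neither did the ependymal (4 rose and 5 fell of 11, adjusted p = 0.866; median 0.06, mean -0.08), choroid plexus (2 rose and 2 fell of 8, adjusted p = 0.794; median -0.07, mean 0.92) or erythrocyte (1 rose and 4 fell of 6, adjusted p = 0.286; median -0.76, mean 1.15) lists. Counts adjusted over the list alone were the same for these lists. The astrocyte filament gene Gfap rose by 4.24 ± 0.05 while the glutamate transporter gene Slc1a2 fell by 2.54 ± 0.04, and the water channel gene Aqp1 of the choroid plexus list rose by 8.23 ± 0.20.

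Of 24356 genes tested, 14626 changed between vehicle tumor and vehicle naive brain, 7125 higher and 7501 lower in tumor, 9796 of them by at least 1 log2 unit. Of the 32 lists 21 passed, and 13 with an estimated correlation. Scaling to library totals moved the median log2 fold change of all genes by 0.25 and gave 8684 higher and 6192 lower genes, so which direction held more genes depends on the scaling. Changes are relative to TMM.

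In MRX-2843 tumor, interferon, antigen presentation, cell division and matrix genes were lower than in vehicle tumor, and neuron and myelin genes were higher. Axl was at 991 ± 11.7 CPM in vehicle tumor and 47.5 ± 1.23 in MRX-2843 tumor (-4.38 ± 0.06, adjusted p = 1.3e-16), beside 35.5 ± 1.68 and 37.9 ± 1.89 in the naive groups. Ccnd1 fell to 15.6 ± 1.53 CPM (-4.02 ± 0.09, adjusted p = 1.4e-14). Zfta fell to 55.6 ± 1.87 CPM (-2.37 ± 0.06, adjusted p = 6.2e-14) and Rela to 30.3 ± 2.55 CPM (-1.5 ± 0.10, adjusted p = 3e-09). Tyro3 rose by 0.74 ± 0.05 to 256 ± 5.43 CPM (adjusted p = 6.5e-09), with 251 ± 5.61 CPM in vehicle naive brain, and L1cam rose by 1.62 ± 0.07 to 126 ± 0.984 CPM (adjusted p = 2.9e-11).

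Of the drug's own targets, Flt3 was at 7.76 ± 0.782 CPM in MRX-2843 tumor (0.82 ± 0.21, adjusted p = 0.0038), a call that was lost without vehicle tumor library 1 (0.53). Mertk was at 51.1 ± 0.253 CPM (-0.24 ± 0.09, adjusted p = 0.037), and its call was lost without vehicle tumor library 2 (-0.13), MRX-2843 tumor library 1 (-0.25) or MRX-2843 tumor library 2 (-0.25). The ligand genes Flt3l (-3.05 ± 0.16) and Pros1 (-3.33 ± 0.11) fell. Over the TAM and FLT3 axis list 5 of 7 genes fell and 2 rose, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.106).

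Fgf15, Fgf4, Hmx1 and Mc2r had no counts in MRX-2843 tumor and were at least 4892-fold, 1467-fold, 2167-fold and 2484-fold lower than in vehicle tumor. Vax2, a homeobox gene, and Ms4a4c also had none, at least 1371-fold and 1078-fold lower. The Y-linked Ddx3y and Eif2s3y were at least 2841-fold and 1911-fold lower, and the X-linked Xist rose by 10.23 ± 0.16 to 766 ± 41.4 CPM. Genes expressed in striatal neurons were among the largest rises, with the dopamine receptor gene Drd2 at 8.23 ± 0.20 and 79.8 ± 2.02 CPM, Syndig1l at 8.51 ± 0.18 and 103 ± 8.55 CPM, and Gpr6 at 29.1 ± 0.214 CPM from 1 count in vehicle tumor, a ratio of 2543 (95% counting interval 704 to 20996). Ccdc187, Serpina9, Cartpt and Gpr101 completed the largest rises.

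Immune, vascular and matrix genes fell in MRX-2843 tumor. All 20 interferon response genes (median -6.63, adjusted p = 1.6e-10), all 15 antigen presentation genes (median -4.21, adjusted p = 4.02e-08), all 10 homeostatic microglia genes (median -2.13, adjusted p = 7.85e-06) and all 15 disease-associated microglia genes (median -2.79, adjusted p = 3.36e-07) fell. Log2 fold changes were -8.28 ± 0.14 for Oas2, -4.72 ± 0.05 for B2m, -3.30 ± 0.07 for Tmem119 and -8.46 ± 0.12 for Gpnmb. Extracellular matrix genes fell in 15 of 16 cases (median -4.13, adjusted p = 4.02e-08; Spp1 -8.87 ± 0.10). Mural and fibroblast markers fell in 7 of 9 (adjusted p = 0.000209; Col1a1 -9.66 ± 0.10) and endothelial markers in 8 of 9 (adjusted p = 0.000658; Vwf -2.84 ± 0.12). Macrophage and monocyte markers fell in 10 of 12 (adjusted p = 0.00019; Lyz2 -4.04 ± 0.11). Erythrocyte genes fell in 6 of 6 (adjusted p = 0.000948; Hba-a1 -3.33 ± 0.10), but they were also lower in MRX-2843 than in vehicle naive brain. Their median in vehicle tumor against naive brain was -0.757, so this fall was not particular to the tumor libraries. Adjusted over the list alone these counts were the same, except for 8 mural and fibroblast markers. Of T and NK cell markers 8 of 10 fell and 1 rose (adjusted p = 0.0108, and adjusted p = 0.0808 with an estimated correlation), the riser being Cd4 (3.58 ± 0.17). Of B cell markers 5 of 6 fell (adjusted p = 0.0117, and adjusted p = 0.0822 with an estimated correlation; Jchain -3.72 ± 0.30), both with the same counts adjusted over the list alone. In these libraries the share of mitochondrially encoded genes moved with the lists, from 3.26 and 3.37% in vehicle tumor to 17.3 and 16.4%.

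Proliferation genes fell as well. All 20 mitosis genes (median -3.00, adjusted p = 1.33e-06), all 16 cell cycle kinases (median -2.39, adjusted p = 1.82e-05) and 16 of 18 S phase genes (median -2.39, adjusted p = 4.62e-06) fell, with the same counts adjusted over the list alone. Mki67 went from 74.7 ± 0.524 to 6.79 ± 1.34 CPM (-3.46 ± 0.16), beside 1.13 ± 0.150 in MRX-2843 naive brain. Neuron markers rose in 11 of 12 cases and 1 fell (median 4.27, adjusted p = 9.67e-07), and oligodendrocyte markers rose in 10 of 10 (median 5.24, adjusted p = 4.4e-07), again the same adjusted over the list alone. Snap25 reached 1155 ± 41.2 CPM, beside 1161 ± 31.4 in MRX-2843 naive brain, and Mbp reached 7027 ± 389 CPM.

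Of ependymal markers 8 of 11 rose and 1 fell (adjusted p = 0.0106, and adjusted p = 0.0808 with an estimated correlation), including the cilia transcription factor gene Foxj1 (1.64 ± 0.25). NF-kB targets fell in 16 of 20 cases and 2 rose (adjusted p = 0.000455, and adjusted p = 0.0917 with an estimated correlation; Icam1 -6.65 ± 0.10). Listed fusion targets fell in 10 of 13 and 2 rose (adjusted p = 0.0059, and adjusted p = 0.0808 with an estimated correlation; Igf2 -9.13 ± 0.16). The p53 and apoptosis genes fell in 14 of 18 and 2 rose (adjusted p = 0.00135; Cdkn1a -1.48 ± 0.09). MAPK feedback genes fell in 10 of 15 cases and 3 rose (adjusted p = 0.012, and adjusted p = 0.0808 with an estimated correlation; Spry4 -3.76 ± 0.17). Receptor tyrosine kinases fell in 19 of 31 with 8 rising (adjusted p = 0.0162, and adjusted p = 0.212 with an estimated correlation; Fgfr1 -2.88 ± 0.07). Adjusted over the list alone the counts were the same, except for 17 falling NF-kB targets. The stress, neutrophil, oligodendrocyte precursor, astrocyte, immediate early, progenitor, hypoxia, cholesterol and choroid plexus lists did not pass (adjusted p = 0.106 to 0.931), and the choroid plexus median of 0.11 and mean of -0.60 differed in sign.

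In all 14715 genes changed between MRX-2843 tumor and vehicle tumor, 7450 higher and 7265 lower in MRX-2843 tumor, and 14225 without genes on X and Y. Of the lists 22 passed, and 15 with an estimated correlation. Treatment here moved together with sex-linked expression, the number in the column names and the neuron markers, and library totals shifted the median by -0.22. With that scaling 6412 genes were higher and 8647 lower, the reverse balance.

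**Figure D2:**
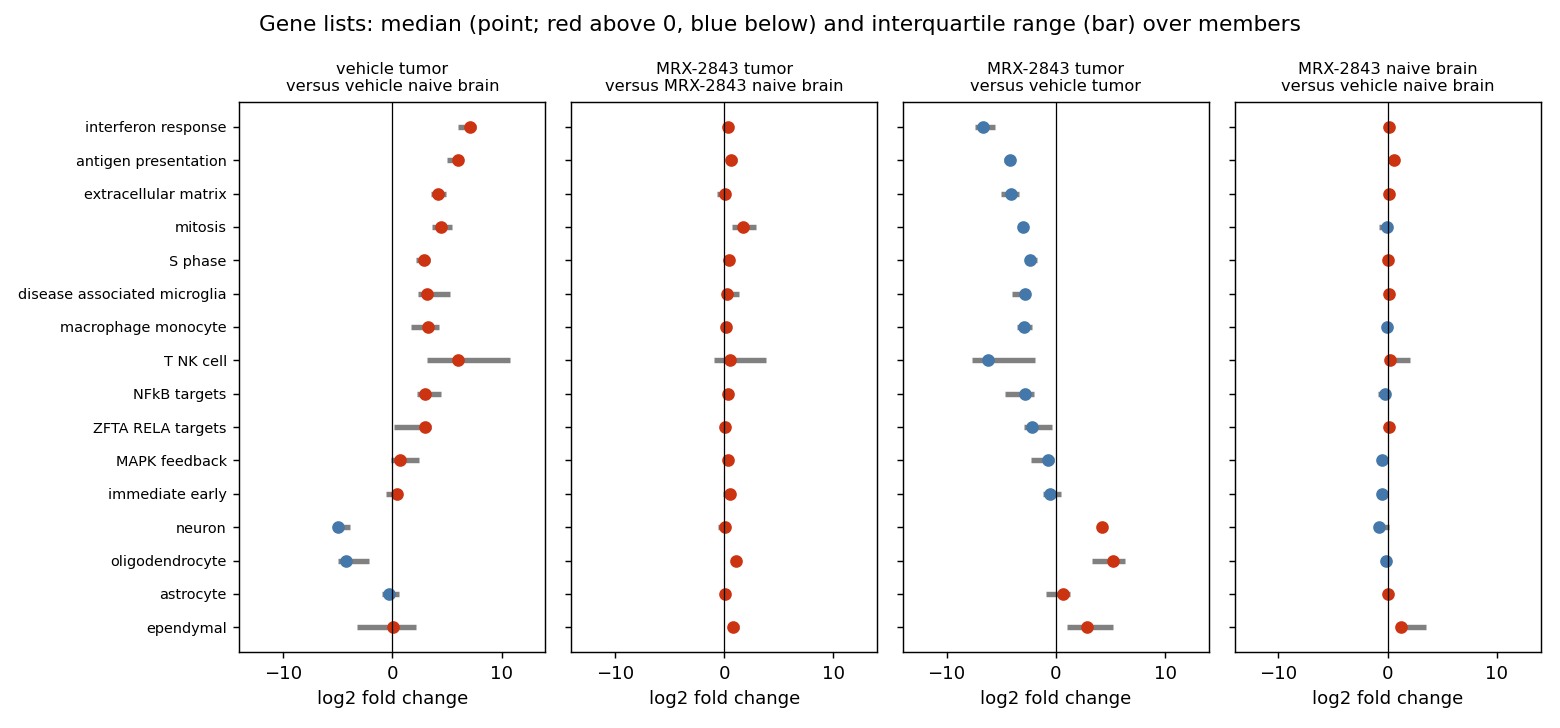
Median log2 fold change (point, red above 0 and blue below) and interquartile range over members (grey bar) of gene lists, 1 panel per comparison of groups, on a linear axis. The interferon response list lies at a median of 7.06 for vehicle tumor against naive brain and at -6.63 for MRX-2843 tumor against vehicle tumor.

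Between MRX-2843 tumor and MRX-2843 naive brain the differences were smaller, with higher myelin and cell division genes in the tumor libraries and a median neuron marker difference of 0.08. All 10 oligodendrocyte markers rose (median 1.05, adjusted p = 5.2e-09, and adjusted p = 0.0668 with an estimated correlation), among them Mal by 1.5 ± 0.07. Of 20 mitosis genes 14 rose, and 15 adjusted over the list alone (median 1.70, adjusted p = 1.13e-06, and adjusted p = 0.0668 with an estimated correlation). Top2a rose by 5.72 ± 0.35 to 8.23 ± 1.81 CPM, beside 76.5 ± 1.44 in vehicle tumor, and Mki67 by 2.55 ± 0.19. Of 15 antigen presentation genes 11 rose, and 12 adjusted over the list alone (median 0.61, adjusted p = 1.52e-05, and adjusted p = 0.072 with an estimated correlation; H2-Ab1 1.76 ± 0.13).

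Among the largest falls were hypothalamic neuropeptide genes, Avp (vasopressin) from 90.7 ± 7.86 CPM (-7.55 ± 0.36) and Oxt (oxytocin) from 60.1 ± 4.07 CPM (-6.96 ± 0.30). Vax2 and Gcgr had no counts in the tumor libraries and were at least 12.7-fold and 7.47-fold lower. Genes with no counts in MRX-2843 naive brain were also higher in the tumor libraries, Hcar2 (at least 19.6-fold), Ntf5 (at least 16.1-fold), Spon2 (at least 11.6-fold) and Igf2os (at least 6.24-fold), bounds that lie below the rise of Top2a. The calls of Igf2os and Ntf5 were lost without MRX-2843 naive library 2 (adjusted p = 0.0699 and adjusted p = 0.0661), and that of Ntf5 also without MRX-2843 tumor library 2 (adjusted p = 0.256). Of neuron markers 4 rose and 4 fell of 12, and 6 and 4 adjusted over the list alone (median 0.08, adjusted p = 0.771): Slc17a7, a cortical glutamate transporter gene, rose by 2.40 ± 0.05 and Gad2, of inhibitory neurons, fell by 1.40 ± 0.07. Beside these lists, region markers were listed after first results had been seen. Of 9 cortex markers 8 rose and 1 fell (median 2.05), and 10 of 13 hypothalamus markers fell (median -5.26). Striatum markers moved little, with 4 of 10 lower (median -0.077). Of 6 thalamus markers 1 rose and 3 fell (median -0.248), and 2 of 5 measured cerebellum markers fell (median -1.17).

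Differences in the receptor and fusion genes were under 1 log2 unit. Axl rose by 0.32 ± 0.06 (adjusted p = 0.00071), Tyro3 by 0.78 ± 0.05 (adjusted p = 7.2e-08) and Zfta by 0.75 ± 0.06 (adjusted p = 6.4e-07). Rela (0.24 ± 0.10, adjusted p = 0.0966) and L1cam (-0.18 ± 0.07, adjusted p = 0.0729) did not pass. Rela passed without MRX-2843 naive library 1 (0.37) and L1cam without MRX-2843 naive library 2 (-0.26), vehicle tumor library 1 (-0.18) or vehicle tumor library 2 (-0.18), and with no filter (adjusted p = 0.048). Ccnd1 was called at 0.33 ± 0.09 (adjusted p = 0.0145) and lost without MRX-2843 naive library 2 (0.31) or MRX-2843 tumor library 1 (0.23) and with only the 2 groups compared (adjusted p = 0.0924). Mertk, called at 0.37 ± 0.09 (adjusted p = 0.0094), was lost without MRX-2843 naive library 2 (0.26). Flt3 was called at -0.61 ± 0.21 (adjusted p = 0.045), and the call was lost without MRX-2843 naive library 2 (-0.46), MRX-2843 tumor library 1 (-0.51), MRX-2843 tumor library 2 (-0.71) or vehicle naive library 2 (-0.61). At nearly the same fold change it was also lost with median-of-ratios scaling (adjusted p = 0.0537), library totals (adjusted p = 0.0607), DESeq2 (adjusted p = 0.0641), the block on the number in the column names (adjusted p = 0.0674) and without mitochondrial genes (adjusted p = 0.0571).

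Further lists passed with medians of 0.27 to 0.83, the highest that of the ependymal markers. The immediate early, MAPK feedback and cholesterol lists were lower in MRX-2843 than in vehicle naive brain, while ependymal markers were higher there. Both comparisons share the MRX-2843 naive libraries, and region markers differed between the MRX-2843 tumor and naive pieces. A rise here may thus reflect the naive pieces rather than the tumor. Immediate early genes rose in 9 of 17 cases and 1 fell (adjusted p = 0.00114, and adjusted p = 0.18 with an estimated correlation; Arc 1.5 ± 0.08). Homeostatic microglia genes rose in 7 of 10 (adjusted p = 0.0015, and adjusted p = 0.148 with an estimated correlation; Cx3cr1 0.48 ± 0.06). Ependymal markers (2 of 11), S phase genes (10 of 18), oligodendrocyte precursor markers (4 of 7), cholesterol synthesis genes (9 of 18) and MAPK feedback genes (8 of 15, with 1 falling) each rose at adjusted p = 0.014, and each gave adjusted p = 0.148 with an estimated correlation. Progenitor genes rose in 7 of 11 cases and 1 fell (adjusted p = 0.014, and adjusted p = 0.168 with an estimated correlation; Vim 0.83 ± 0.05). Interferon response genes rose in 8 of 20 and 1 fell (adjusted p = 0.0151, and adjusted p = 0.148 with an estimated correlation; Gbp2 1.21 ± 0.12). Cell cycle kinases rose in 8 of 16 cases (adjusted p = 0.0273, and adjusted p = 0.153 with an estimated correlation; Pbk 4.65 ± 0.29). Receptor tyrosine kinases rose in 14 of 31 with 6 falling (adjusted p = 0.0413, and adjusted p = 0.35 with an estimated correlation; Ddr1 0.64 ± 0.07). Adjusted over the list alone the counts were the same, except for 9 rising MAPK feedback genes and 9 rising interferon response genes. Without MRX-2843 naive library 2 the cholesterol (adjusted p = 0.0526), interferon (adjusted p = 0.0526), MAPK feedback (adjusted p = 0.0531) and receptor (adjusted p = 0.0526) lists no longer passed. The kinase list was lost without vehicle tumor library 1 (adjusted p = 0.0516), vehicle tumor library 2 (adjusted p = 0.0512) or MRX-2843 tumor library 2 (adjusted p = 0.104). The receptor list was also lost without vehicle tumor library 1 (adjusted p = 0.0952), vehicle tumor library 2 (adjusted p = 0.0965), MRX-2843 naive library 1 (adjusted p = 0.0503) or MRX-2843 tumor library 1 (adjusted p = 0.13), and with the replicate block (adjusted p = 0.0562).

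In this comparison 5935 genes changed, 3027 higher and 2908 lower in tumor, 1363 of them by at least 1 log2 unit. With only the 2 groups compared the balance turned, to 2948 higher and 3043 lower. Of the lists 14 passed limma's camera test with the preset correlation and 0 with an estimated one, where 10 had an unadjusted p under 0.05. The latter setting also has fewer degrees of freedom. The median, mean or test of the neutrophil, p53, matrix, erythrocyte, T and NK cell, TAM and FLT3 axis and endothelial lists differed in sign, and none of these passed. The stress, integrated stress response and heat shock list (8 of 15 fell and 2 rose, adjusted p = 0.0801) passed as lower without MRX-2843 tumor library 2 (adjusted p = 0.0465), and NF-kB targets (5 of 20 rose and 2 fell, adjusted p = 0.136) passed as higher without MRX-2843 naive library 1 (adjusted p = 0.0108). Counts adjusted over the list alone were the same for both.

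Naive brain differed between MRX-2843 and vehicle mice in sex-linked genes and in the neuropeptide genes Avp and Oxt, and no gene list passed with an estimated correlation. Ddx3y, Eif2s3y, Kdm5d and Uty had no counts in MRX-2843 naive brain, at least 1722-fold, 3031-fold, 1017-fold and 485-fold lower, and Xist was higher by 7.73 ± 0.14. Avp rose by 7.73 ± 0.36 (adjusted p = 1.2e-09) and Oxt by 8.53 ± 0.34 (adjusted p = 2.9e-10). Fgf15 was at least 6.45-fold higher from no counts in vehicle naive brain, at 0.192 ± 0.192 CPM, a call that was lost without vehicle naive library 1 (adjusted p = 0.0572) or vehicle naive library 2 (adjusted p = 0.0545). Axl (0.10 ± 0.06, adjusted p = 0.27), Mertk (-0.11 ± 0.09, adjusted p = 0.485), Flt3 (0.25 ± 0.21, adjusted p = 0.463), L1cam (0.11 ± 0.07, adjusted p = 0.316) and Rela (0.01 ± 0.10, adjusted p = 0.996) did not pass. Ccnd1 (-0.70 ± 0.09), Tyro3 (-0.76 ± 0.05) and Zfta (-0.55 ± 0.06) fell.

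Markers of brain regions, listed after first results had been seen, differed between the naive groups. In the MRX-2843 group 10 of 13 hypothalamus and 10 of 10 striatum markers were higher (medians 4.73 and 2.56) and 8 of 9 cortex markers lower (median -2.87). Immediate early genes fell in 12 of 17 cases (median -0.55, adjusted p = 8.43e-07, and adjusted p = 0.129 with an estimated correlation), with Egr1 at -0.85 ± 0.06 and Nr4a1 at -1.0 ± 0.07. Erythrocyte genes fell in 5 of 6 cases (median -3.64, adjusted p = 1.25e-05, and adjusted p = 0.129 with an estimated correlation), the alpha globin gene Hba-a1 from 302 ± 13.8 to 23.5 ± 3.47 CPM (-3.69 ± 0.10). MAPK feedback genes fell in 8 of 15 cases (median -0.53, adjusted p = 0.000486, and adjusted p = 0.129 with an estimated correlation; Etv5 -1.09 ± 0.09). Cholesterol synthesis genes fell in 8 of 18 (adjusted p = 0.031, and adjusted p = 0.213 with an estimated correlation; Hmgcs1 -0.54 ± 0.06). Antigen presentation genes rose in 11 of 15 cases, and 12 adjusted over the list alone (median 0.57, adjusted p = 0.000171, and adjusted p = 0.129 with an estimated correlation; B2m 0.47 ± 0.05). Neuron markers fell in 8 of 12 cases and 3 rose (adjusted p = 0.00155, and adjusted p = 0.129 with an estimated correlation), with Slc17a7 at -3.49 ± 0.05 and Gad2 at 1.60 ± 0.07. Ependymal markers rose in 4 of 11 cases and 1 fell, and 5 and 1 adjusted over the list alone (adjusted p = 0.00288, and adjusted p = 0.129 with an estimated correlation; Ccdc153 4.73 ± 0.89). Adjusted over the list alone the other counts were the same, except that 1 cholesterol gene also rose. The cholesterol call was lost without vehicle naive library 1 (adjusted p = 0.0607) or MRX-2843 naive library 2 (adjusted p = 0.0974).

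In naive brain 5225 genes changed, 2383 higher and 2842 lower in the MRX-2843 group, 5013 without genes on X and Y, and 1389 by at least 1 log2 unit. Of the lists 7 passed limma's camera test, and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05. The S phase, mural, B cell, choroid plexus, cell cycle kinase, macrophage and homeostatic microglia lists had medians, means or tests of differing sign and did not pass.

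The tissue contrast itself differed between treatments for the tumor's main genes. The interaction, the tumor minus naive difference under MRX-2843 less that under vehicle, was -4.48 ± 0.08 for Axl (adjusted p = 3.4e-15), -3.32 ± 0.12 for Ccnd1 (adjusted p = 7.1e-12), -1.82 ± 0.09 for Zfta (adjusted p = 9.9e-11) and -1.51 ± 0.14 for Rela (adjusted p = 2.3e-07). Tyro3 (1.5 ± 0.07) and L1cam (1.51 ± 0.10) went the other way. Dlk1, an imprinted gene, was at 4900 ± 4.16 CPM in vehicle tumor, 2.88 ± 0.341 in MRX-2843 tumor, and 1.05 ± 0.386 and 52.5 ± 1.83 in vehicle and MRX-2843 naive brain (-16.37 ± 0.16). Smim43, Hs3st2, Igfn1 and Hkdc1 had the largest positive interactions, with Hkdc1 at 8.63 ± 0.33. Mertk (-0.13 ± 0.13, adjusted p = 0.449) and Flt3 (0.56 ± 0.29, adjusted p = 0.128) did not pass, though Mertk passed with library totals (-0.35) and Flt3 without vehicle tumor library 2 (0.91).

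The interaction passed for 12563 genes, 6401 positive and 6162 negative, and for 19 of 32 lists, 11 of them with an estimated correlation. With library totals the median shifted by -0.22 and the balance turned, to 5534 positive and 7402 negative genes. Interferon response genes had a negative interaction in 20 of 20 cases (median -6.42, adjusted p = 4.4e-11) and neuron markers a positive one in 12 of 12 (median 4.86, adjusted p = 1.98e-08), the same adjusted over the list alone. Across the 24356 genes the vehicle and MRX-2843 tissue contrasts, which share no library, correlated at r = 0.003 (genes are not independent replicates). Genes called in both contrasts went the same way more often than independent lists would, 1294 higher in both against 886 expected and 1461 lower in both against 896. Opposite calls were also above that expectation, 880 higher under vehicle and lower under MRX-2843 against 851, and 1347 the other way against 932.

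**Figure D3:**
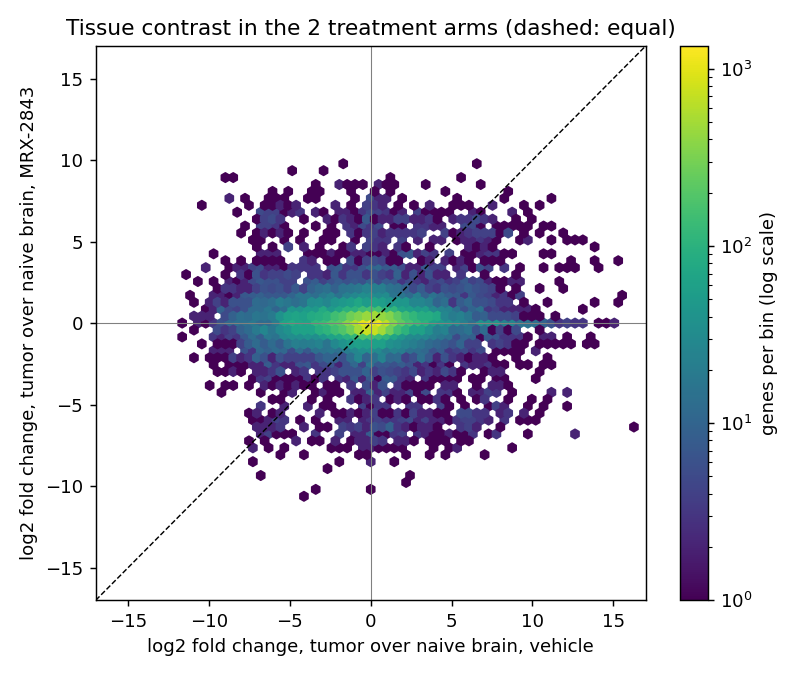
Log2 fold change of tumor against naive brain under vehicle (horizontal axis) and under MRX-2843 (vertical axis), as the number of genes per hexagon on a log color scale, with a dashed line where both are equal. The genes spread along the horizontal axis, with r = 0.003 across 24356 genes.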

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

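Of the tests in this part, those of the drug within unchanged tumor content, of exchanged labels, of brain regions and of neurogenic tissue were chosen after the result had been seen.

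The tumor against naive brain difference changed with treatment, by the test of the interaction, for 12563 genes and 19 gene lists. The lists with a negative interaction were interferon response (adjusted p = 4.4e-11), antigen presentation (adjusted p = 9.62e-09), extracellular matrix (adjusted p = 1.02e-08), disease-associated microglia (adjusted p = 9.55e-08), mitosis (adjusted p = 9.55e-06), S phase (adjusted p = 6.87e-05), cell cycle kinases (adjusted p = 8.38e-05), macrophages and monocytes (adjusted p = 0.000304) and mural cells and fibroblasts (adjusted p = 0.000327). Neuron (adjusted p = 1.98e-08) and oligodendrocyte markers (adjusted p = 9.44e-08) had a positive one. Some lists with a negative interaction lost their call in camera's test with an estimated correlation. Among them were homeostatic microglia (adjusted p = 9.55e-06) and endothelial markers (adjusted p = 0.00114), both at adjusted p = 0.0541 with an estimated correlation. NF-kB targets (adjusted p = 0.00155) and listed fusion targets (adjusted p = 0.00739) were at adjusted p = 0.138 and adjusted p = 0.0949 with it. The same held for p53 and apoptosis genes (adjusted p = 0.00739, and adjusted p = 0.0856 with an estimated correlation), T and NK cells (adjusted p = 0.00806, and adjusted p = 0.0867 with an estimated correlation), receptor tyrosine kinases (adjusted p = 0.00894, and adjusted p = 0.206 with an estimated correlation) and B cells (adjusted p = 0.0134, and adjusted p = 0.0997 with an estimated correlation).

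Of single genes, the log2 interaction passed for Axl (-4.48), Ccnd1 (-3.32), Zfta (-1.82), Rela (-1.51), Tyro3 (1.5) and L1cam (1.51), and was largest among those named for Smim43 (10.42), Hs3st2 (9.32), Igfn1 (9.17) and Hkdc1 (8.63) on the positive side. On the negative side it was -16.37 for Dlk1, and fitted values of -22.58 for Fgf15, -16.20 for Vax2 and -14.86 for Gcgr, which rest on groups with no counts and are no bounds.

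The first pattern is that the MRX-2843 tumor libraries resembled naive brain. A change of expression within tissue of unchanged tumor content is argued against by the neuron markers, whose median log2 difference from MRX-2843 naive brain was 0.080, against -5.01 for vehicle tumor and naive brain. An exchange of the tumor and naive labels within the MRX-2843 libraries is argued against too, since the MRX-2843 naive libraries correlated with vehicle tumor at r = 0.639 at most. The 344 genes at least 32 times higher in vehicle tumor than in both naive groups reached a median of 1.46% of the vehicle tumor level in MRX-2843 tumor, as tissue that is mostly brain would give. Of these genes 14 were above 10% of that level there. The medians were 1.00% in MRX-2843 and 0.933% in vehicle naive brain. The choice of genes held both naive values low in advance, so they are no independent reference. Whether the drug had removed the tumor, the piece taken missed it, or the samples were labelled with another identity stays open, since treatment, the number in the column names and sex-linked expression coincide.

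The second pattern is that mitosis genes were higher in MRX-2843 tumor than in MRX-2843 naive brain. A small share of RNA from tissue like the vehicle tumor is argued against, because the excess over naive brain was a median of 7.83% of the vehicle tumor level for 20 mitosis genes and 0.291% for 334 other tumor-high genes, a ratio of 26.9. The mitosis list was singled out for being higher in these libraries, and its genes vary together, so no p-value is given. A candidate explanation is more neurogenic tissue in the tumor piece: 8 of 13 neuroblast markers rose and 2 fell (Tubb3 -0.71 and Dlx5 -0.75), with a median of 0.67. Of these markers 3 are also in the progenitor list and had been seen, and the other 10 had a median of 0.71, with Igfbpl1 at 2.46 and Cd24a at 1.61. Dividing tumor cells that lack the other tumor-high genes stay open and were not tested.

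The third pattern is the difference between the naive brain groups. Leaving out genes on the sex chromosomes removed 4.06% of the changed genes, so most of the changed genes lie elsewhere. The same step took 14626 changed genes to 14122 between vehicle tumor and vehicle naive brain. X and Y genes are a small part of those tested, so a large loss was not possible from the start. This step does not test an effect of sex on other genes. A candidate explanation is that the pieces came from different brain regions. Hypothalamus markers had a median difference of 4.73 (10 of 13 higher in the MRX-2843 group, such as Avp at 7.73), striatum markers 2.56 (10 of 10 higher) and cortex markers -2.87 (8 of 9 lower). Thalamus markers (median 0.25, 3 of 6 higher and 1 lower) and cerebellum markers (median 0.81, 2 of 5 measured higher) moved less. An effect of the drug or of the animals' sex on the other genes stays open, as neither can be separated from the number in the column names.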

How the results depend on the processing

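Fits without X and Y genes, without mitochondrial genes and copies and without both MRX-2843 tumor libraries, and library totals for lists, were chosen after seeing the data. Counts of changed genes stayed within 1.5 times of the main count with another scaling, filter or test, with each block and in the fits added later: 13038 to 14932 for vehicle tumor against naive brain, 5565 to 6444 for MRX-2843 tumor against naive brain, 13681 to 15059 for MRX-2843 against vehicle tumor, 5013 to 5795 for naive brain and 11542 to 12936 for the interaction. Which direction held more genes was less stable, as a stricter filter and a fit of only the 2 groups also turned it for vehicle tumor against naive brain (6823 higher and 6815 lower, 7680 and 7252) and for MRX-2843 against vehicle tumor (6750 and 6931, 7173 and 7526), and the fit of 2 groups for MRX-2843 tumor against naive brain (2948 and 3043). It also turned without both MRX-2843 tumor libraries for vehicle tumor against naive brain (7356 and 7327), without mitochondrial genes (7333 and 7362), vehicle naive library 2 (7223 and 7237) or MRX-2843 tumor library 2 (6713 and 6822) for MRX-2843 against vehicle tumor, and without the latter for the interaction (5943 and 5990). DESeq2 gave 14689, 6020, 14832, 5400 and 12643. It made 77 false calls among 230 on simulated data, drawn with edgeR's estimates of spread and with few genes changed. Whether that share holds for the real counts was not tested. Leaving out each library in turn gave 13098 to 14643, 4666 to 6390, 13389 to 14767, 3835 to 5684 and 11582 to 12064 genes, and 21, 10 to 14, 22, 6 to 7 and 19 lists, where a lost list was in some fits replaced by MAPK feedback, NF-kB targets or the stress list. A minimum of 1 log2 unit left 9796, 1363, 9706, 1389 and 8894 genes, fewer by its own construction. With an estimated correlation 13, 0, 15, 0 and 11 lists passed limma's camera test, and 16, 10, 19, 7 and 16 had an unadjusted p under 0.05. For lists estimated below the preset 0.01, such as antigen presentation (-0.0610) and mitosis (-0.0305), a stronger correlation is argued against as the cause. Other lists, such as immediate early genes (0.118), were estimated above it. In MRX-2843 tumor against naive brain, the unadjusted p of camera's test for mitosis went from 7.06e-08 to 0.00418 with the estimated correlation. For the oligodendrocyte list, estimated at 0.00983 and so close to the preset value, it went from 1.62e-10 to 0.00306. For these lists the values argue for the 4 residual degrees of freedom of this setting as the cause. For lists estimated above 0.01 the causes were not separated. Duplicate numbers share only a number, since residuals of duplicates 1 and 2 correlated at -0.00667 to 0.0176 between groups, and a replicate block gave 14120, 5759, 14226, 5067 and 12113 genes and 21, 13, 22, 7 and 19 lists. A block on the number in the column names could not be fitted for the contrasts of treatments.

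In naive brain, values near 0 changed sign. Rela (0.01) was at -0.0163 with median-of-ratios scaling, -0.0145 in DESeq2, -0.00466 with the 2 groups alone, -0.0155 without mitochondrial genes and -0.00487 without both MRX-2843 tumor libraries, and at -0.128 to 0.137 with 1 library left out. Ighm (-0.02) was at -0.142 to 0.0716 with 1 library left out, and neither gene passed in any of these. Ccl2, called lower in the MRX-2843 group, ran from -7.83 to 0 with 1 library left out, and was at 0 without vehicle naive library 2, which held all its counts in naive brain. The cause was not tested for Rela and Ighm. The calls of the main fit are limited to the 24356 genes that passed the filter, where the fit without a filter tested 34236. In simulated data at this spread, with few genes changed, changes of 1.5-fold were recovered in 32.8% of genes. The cut-off on p is looser where many genes change, so this share is not the sensitivity of the main fit.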

Other observations

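The genes around Ccnd1 were looked at after the values of Ccnd1, Fgf4 and Fgf15 had been seen, so this part was chosen after the result. Within 500 kb on each side of Ccnd1 on chromosome 7, 18 genes were tested between vehicle tumor and vehicle naive brain, of which 14 were higher and 2 lower. Without the 3 genes that prompted the look it was 11 of 15 higher (73.3%), beside 29.3% of all 24356 genes tested. Among these 11, Gm26793 and Gm39119 overlap Fgf15 and LTO1 overlaps Ccnd1 in position. The 73.3% is thus not free of the genes left out. Neighbouring genes are not independent, so no test was made. Besides Fgf4 and Fgf15, a further fibroblast growth factor gene, Fgf3 (144838083 to 144844436), was higher by 9.65 ± 0.22, at 271 CPM in vehicle tumor and 0.333 in vehicle naive brain. Fadd was higher by 2.31 ± 0.26, Tpcn2 by 2.26 ± 0.18 and Mrgprf by 3.35 ± 0.35, while Cttn, at the edge of the window, was higher by 0.37 ± 0.06. Bc1, a neuronal RNA, was lower by 3.95 ± 0.22 in tumor. In MRX-2843 tumor Fgf3 was at 1.83 CPM, beside 2.71 in MRX-2843 naive brain.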
